A study of Mus musculus with 12 samples.

How the data were processed

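Expression was measured in the ipsilateral hippocampus of mice on 12 Affymetrix Mouse MG-430 PM array strips, 3 in each of 4 groups (control and KA at 8 h and at 14 d). Per the labels, 5 ng of total RNA was amplified over 22 cycles and 8 µg of cDNA was labelled. The values are log2 intensities that the authors made with RMA before they were deposited, since the labels name RMA and affy, with no version, role or order. The deposited table does not state its scale, and its values between 2.63 and 13.2 with near-equal array medians have the range of RMA output. Groups were taken from the sample titles. The titles' first word, Input, is not explained in the labels and was not interpreted.

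The table holds 45141 probe sets, of which 104 are array controls. Of the other 45037, 28898 carried 1 gene symbol, 551 carried several and 15588 were not named by the probe annotation used here, which dates from an older release. Symbols were checked by gene identifier against the mouse annotation (assembly GRCm38.p6), which served only for names and chromosomes. For each of 17097 genes, the probe set with the highest mean over the 12 arrays was used, and 6673 of the genes tested had several. Genes were kept when above the 30th percentile of the array (4.08 to 4.15, log2) on at least 3 arrays, which left 13853. Mean levels of GC-rich background probe sets were 4.34 ± 0.16 (SD, n = 3) in the 8 h controls, 4.28 ± 0.18 in the KA group at 8 h, 4.34 ± 0.14 in the 14 d controls and 4.53 ± 0.23 in the KA group at 14 d. Where an array of the dimmer group lay at or below the mean of its own GC-rich background probe sets, that mean took the place of its value and the fold was written as "at least", a choice made after the values were seen. No pair of arrays was identical.

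All 12 arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean per group, 8 residual degrees of freedom and eBayes. The comparisons were KA minus control at 8 h and at 14 d, the difference of these changes, and the 14 d controls minus the 8 h controls. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a gene called at an adjusted p under 0.05. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 35 lists with at least 5 measured genes, and with an estimated correlation and fry beside it. The overlap of the changes was set against the number independent lists would share. The comparisons, the 37 gene lists, the filter and the naming rule were fixed before the data were examined. The lists hold 590 entries, of which 478 were measured. After the data were seen, 6 further lists were added.

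The naming rule took, at 8 h and at 14 d, the 6 largest rises and the 6 largest falls among genes past the threshold with no overlap between groups, and up to 3 members of each called list and up to 2 of each other list by adjusted p. Fos, Arc, Bdnf, Npy, Gfap, Il1b, Aif1, Gad1, Calb1 and Cpeb4 were named whatever their result. For the difference of changes and the control groups, 4 genes each way were named. Predicted genes and clones were skipped, and some list members under the rule were left out of the text. Members named beyond the rule were chosen after their values were seen.

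Replicate numbers are shared between groups, and the labels do not say that they pair samples. As a check, the deviations of arrays with the same number from their group means were correlated. At 8 h the correlations were 0.155, 0.138 and 0.413, all above the bound set for a pairing, which therefore comes from the data alone. Of the 6 arrays at 8 h, 3 correlated best with the array of their own number, and control 8 h replicate 1 correlated more closely with KA 8 h replicate 2 (0.163) than with replicate 1. With the replicate number as a block (paired), genes changed at 8 h numbered 3076, of which 2414 were shared with the 2420 of the fit without it. The blocked count was seen in the same run as the correlations. At 14 d the correlations did not all reach the bound. The third arrays of the 4 groups correlated with each other at 0.401 to 0.526. They hold 1 array per group, which allows no test among them alone.

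The fit was tested on simulated data of the same design with 13853 genes. Changes of log2 size 0.5, 1 and 2 were added to 67, 67 and 66 of them, and a further 20 moved together by 0.5. This is a smaller share than the 17.5% called at 8 h, so the recovery figures do not carry over to that share. The noise was drawn independently for each gene and array. Deviations that arrays share, as the third arrays do, are therefore not covered by the figures that follow. At a log2 size of 1, it recovered 97.0% at 8 h, 95.5% at 14 d, 86.6% for the difference of changes and 97.0% between controls. False calls numbered 15, 7, 7 and 15, which were 7.25%, 3.5%, 4.22% and 7.39% of the calls. At a size of 0.5, recovery was 71.6%, 74.6%, 44.8% and 68.7% in that order. Alternatives covered the filter, the choice of probe set, the arrays in the fit, the replicate block, median centring, cyclic loess, a trended and robust prior, array weights, the thresholds, the set test, and each array left out in turn. Leaving out the X and Y chromosomes and leaving out the third array of each group were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Probe sets without a symbol or with several were left out of the gene tests.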

Results

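Gene expression was measured in the mouse hippocampus on the side of an injection into the amygdala. Kainic acid (KA), an agonist of kainate-type glutamate receptors, was given there at 0.3 µg in 0.2 µl to set off status epilepticus, a long-lasting seizure. Lorazepam, a benzodiazepine that dampens seizures, followed at 6 mg/kg into the abdomen 40 min after KA. Control mice received 0.2 µl of vehicle in the amygdala, and the labels do not say whether they were given lorazepam. Tissue was taken at 8 h or 14 d, which gave 4 groups (control and KA at each time) of 3 arrays each. For the 6 arrays titled as 8 h, a separate time entry in the labels runs from 8 to 13 h. It is 8 to 10 h for the controls and 11 to 13 h for the KA arrays. The time in the titles was used. If the separate entry were the true time, time and KA could not be told apart at 8 h. The labels do not say whether each array came from its own animal, so p-values measure only the spread between these samples. The median log2 value of an array lay between 4.90 and 4.95, and arrays of a group correlated with each other at r = 0.989 to 0.997 over probe sets. Precision is limited by the number of arrays, 3 per group.

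The comparison at 8 h shows which transcripts differed in the ipsilateral hippocampus soon after status epilepticus. The 6 largest fitted rises were those of genes induced by activity or by stress. A fold is given as "at least" where an array of the dimmer group lay at or below the background of the array, and is then counted from that background. Fos, which encodes a subunit of the AP-1 transcription factor, was at least 43.4-fold higher after KA (log2 change as fitted 5.49 ± 0.50, SE, n = 3 per group, limma adjusted p = 1.89e-06), with 1 of the 3 control arrays above background. Fosb, which encodes a related subunit, was 34.3-fold higher, and Nptx2, a neuronal pentraxin that clusters AMPA receptors, was 16.9-fold higher. Hspa1b, an inducible heat shock protein, was at least 21.7-fold higher, with 1 of 3 control arrays above background, and Atf3, a transcription factor induced by stress and injury, at least 14.1-fold higher. Inhba, which encodes a subunit of activin A, was 29.7-fold higher at the probe set used, while its other probe set changed by -0.18 (log2). The control arrays of Inhba (4.48 to 4.55, log2) lay above their background but, on replicates 1 and 2 (background 4.47 and 4.40), close to it. The size of its fold is therefore uncertain. The largest falls were those of Dsp (desmoplakin, a marker of dentate granule cells), which was 3.91-fold lower (log2 change -1.97 ± 0.17), and Sphk2 (sphingosine kinase), 3.29-fold lower at the probe set used and changed by 0.01 (log2) at its other one. P2ry12, an ADP receptor of resting microglia, was 2.96-fold lower, Eif2s3y, a Y-linked gene, 2.62-fold lower, Htr1a, the serotonin 1A receptor, 2.50-fold lower, and Ccdc177 2.42-fold lower.

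Of 13853 genes tested at 8 h, 2420 changed (17.5%), of which 1097 rose and 1323 fell. The split of genes changed at 8 h turned with cyclic loess (1402 rose and 1217 fell), without control 8 h replicate 3 (903 and 756), without KA 8 h replicate 1 (959 and 826), at an adjusted p under 0.01 (723 and 629) and with all probe sets tested and no collapse to genes (2452 and 2391). The rises were larger, since 190 genes rose and 13 fell by at least 2-fold. Of the changed genes, 2391 showed no overlap between KA and control arrays. Over all genes 33.8% showed none, where chance gives 10%. With the third array of each group left out, a choice made after seeing the data, genes changed at 8 h numbered 1859 (929 rose and 930 fell).

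Counts in brackets in the accounts of gene lists are adjusted over the list alone. Members named from short lists beyond the naming rule were chosen after their values were seen. Of the immediate early genes at 8 h, 18 of 20 measured rose [18 adjusted over the list alone], with a median log2 change of 2.12 (camera adjusted p = 6.20e-25). Arc, a regulator of AMPA receptor uptake, rose 12.3-fold (log2 change 3.61 ± 0.24), and Nr4a2, an orphan nuclear receptor, 4.80-fold at 4 of 5 probe sets with the same sign. Of the delayed activity-induced genes, 18 of 20 rose [19], with a median of 1.81 (adjusted p = 1.48e-29). Bdnf, a neurotrophin, rose 7.37-fold (log2 change 2.88 ± 0.21), Gadd45g, a DNA damage-inducible gene, 7.39-fold and Pcsk1, a prohormone convertase, 4.53-fold. Neuropeptide genes rose in 6 of 14 cases [6], with a median of 0.28 (adjusted p = 3.07e-05). Crh, corticotropin-releasing hormone, was at least 4.69-fold higher, with 0 of 3 control arrays above background, Nts, neurotensin, at least 3.18-fold, Npy, neuropeptide Y, 2.14-fold and Sst, somatostatin, 1.64-fold.

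Stress and glial genes also moved at 8 h. Heat shock and stress genes rose in 12 of 16 cases [13], with a median of 0.85 (adjusted p = 3.74e-16). Among them, Hspb1, a small heat shock protein, was 4.71-fold higher and Atf4, a factor of the integrated stress response, 1.78-fold higher. Reactive astrocyte genes rose in 16 of 19 cases [16], with a median of 1.02 (adjusted p = 1.37e-21). Osmr, the oncostatin M receptor, was 4.55-fold higher, Cd44, a hyaluronan receptor, 4.41-fold, and Gfap, the astrocyte intermediate filament, 2.03-fold (log2 change 1.02 ± 0.13). Extracellular matrix remodelling genes rose in 5 of 14 cases [5], namely Adamts1, Adamts4, Col3a1, Col4a1 and Plaur, with a median of 0.18 (adjusted p = 0.000202). Adamts1, a matrix protease, was at least 1.98-fold higher. The calls of these 6 lists held with an estimated correlation, but with larger camera adjusted p-values. These were 0.0377 for immediate early, 0.0406 for delayed activity-induced, 0.0376 for neuropeptide and 0.0280 for extracellular matrix genes. They were 0.00926 for heat shock and stress genes and 0.00180 for reactive astrocyte genes.

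The remaining calls at 8 h were lost with an estimated correlation. Activated microglia and phagocyte genes rose in 9 of 20 cases [9], with a median of 0.24 (adjusted p = 4.39e-05, and adjusted p = 0.164 with an estimated correlation). Cd68, a lysosomal protein of phagocytes, was 2.82-fold higher. Complement genes rose in 4 of 8 cases [4] (adjusted p = 0.000664, and adjusted p = 0.177 with an estimated correlation). These were the receptors C5ar1 (3.78-fold) and C3ar1 (3.24-fold), with C1qb and C4b. Cytokine and chemokine genes rose in 3 of 14 cases [5] (adjusted p = 0.00534, and adjusted p = 0.443 with an estimated correlation), namely Ccl3 (2.49-fold), Lif (at least 1.93-fold, with 0 of 3 control arrays above background) and Ccl9. The cytokine Il1b differed by 0.12 ± 0.12 (log2, adjusted p = 0.564), which did not pass.

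Glutamate receptor genes moved down as a list at 8 h, where 5 of 20 fell and 1 rose [7 and 1], with a median of -0.21 (adjusted p = 0.0120, and adjusted p = 0.495 with an estimated correlation). Grik2, a kainate receptor subunit, was 1.48-fold lower, Gria4, an AMPA receptor subunit, 1.43-fold lower, and Gria3, Grm3 and Grm5 also fell, while Grm2 rose. Of the voltage-gated sodium and calcium channel genes, 4 of 17 fell and 1 rose [7 and 1] (adjusted p = 0.0223, and adjusted p = 0.591 with an estimated correlation). The list did not pass without KA 8 h replicate 1 (adjusted p = 0.0595) or 2 (adjusted p = 0.0534). Scn2b was 1.46-fold and Cacna1d 1.44-fold lower, Cacna2d3 and Scn3a fell, and Cacna1g rose. Of the oligodendrocyte and myelin genes, 5 of 13 fell [5] (adjusted p = 0.0350, and adjusted p = 0.591 with an estimated correlation). Mog, a myelin surface protein, was 1.61-fold lower, and Aspa, Cnp, Gjc3 and Ugt8a fell as well. This list did not pass without control 8 h replicate 1 (adjusted p = 0.0968) or KA 8 h replicate 2 (adjusted p = 0.112).

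Other lists at 8 h held changes in both directions and did not pass as lists. With 1 array left out, 4 of the lists that had not passed did so (mitochondrial respiratory chain, poly(A) tail, CA3 pyramidal and synaptic vesicle genes, with adjusted p from 0.0243 to 0.0490). Of 10 homeostatic microglia genes, 5 fell and 1 rose [5 and 1]. P2ry12, Tmem119, P2ry13, Selplg and Csf1r fell, whereas Fcrls was 1.74-fold higher, and the marker Aif1 differed by -0.17 ± 0.12 (log2, adjusted p = 0.407). Of 11 dentate granule cell markers, 3 rose and 4 fell [4 and 5]. Pdzd2 was 2.02-fold higher and Calb1, the calcium buffer calbindin, 1.35-fold lower (log2 change -0.43 ± 0.10, adjusted p = 0.00545). Of 12 voltage-gated potassium and HCN channel genes, 2 rose and 5 fell [2 and 6], with Kcna4 1.85-fold higher and Kcnq3 1.42-fold lower. Of 22 genes of cytoplasmic polyadenylation and the poly(A) tail, 6 rose and 2 fell [6 and 3]. Btg2, which promotes deadenylation, was 2.43-fold higher and Zfp36l1, a binder of AU-rich elements, 2.34-fold higher. The polyadenylation element binding gene Cpeb4 differed by -0.09 ± 0.11 (log2, adjusted p = 0.668).

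Among markers of neurons and neighbouring tissue at 8 h, 4 of 15 interneuron markers fell and 1 rose [4 and 1], 1 of 8 CA1 pyramidal markers fell [2], and 2 of 8 CA3 pyramidal markers rose [2]. These were falls of Erbb4, Kcnc1, Nos1, Pvalb and the CA1 marker Ccn3, and rises of Sst, Nectin3 and Tspan18. Gad1, which makes GABA, had a log2 change of -0.00094 ± 0.11 (adjusted p = 0.999). Its sign turned with median centring, with cyclic loess, and without control 8 h replicate 2, control 8 h replicate 3 or KA 8 h replicate 1, where its change was 0.02, 0.01 and 0.07. Of 8 cortex and amygdala markers, Fezf2 and Rorb rose and Lamp5 fell [2 and 2], and 1 of 9 thalamus markers (Ntng1) fell [1]. None of 10 choroid plexus markers, 7 blood leukocyte markers or 4 erythrocyte markers passed, and none of these 3 lists had a member at an unadjusted limma p under 0.05. Of 16 endothelial and mural markers, 2 rose and 3 fell [4 and 4], and of 13 astrocyte markers 1 rose and 2 fell [1 and 2]. Of 7 oligodendrocyte precursor markers, Sox10 rose and Olig1 fell [1 and 1].

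Of the lists for cell functions at 8 h, 1 of 10 GABA-A receptor genes fell [1] and 2 of 14 purinergic and adenosine genes fell [2], namely Gabrg3, Adk and P2ry12. Of 17 synaptic vesicle genes, Syt4 rose and Rab3a and Synpr fell [1 and 4], and of 11 interferon response genes Ifit3 fell [3]. Of 11 neurogenesis genes, Sox11 rose and Hopx and Tubb3 fell [1 and 2], and Aurka and Ccnd1 rose among 16 cell cycle genes [2]. Of 11 cholesterol synthesis genes, Cyp51, Idi1 and Sc5d rose and Dhcr7 fell [3 and 1]. Ndufv1 fell among 19 mitochondrial respiratory chain genes [1], and Rplp0 rose among 10 reference genes [1]. Median and mean differed in sign for astrocyte markers, neurogenesis genes, cell cycle genes, and cortex and amygdala markers, and for the untested sex-linked genes.

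Some of the smaller calls at 8 h ended when 1 of the 12 arrays was left out. Of 76 further genes called at 8 h and named in the text, the members of added lists included, 26 lost their call so, with an adjusted p up to 0.211 (Dhcr7 without KA 8 h replicate 1) in a range from 0.000411 over all alternatives. They were Gria3, Grm2, Cacna2d3, Scn3a, Cacna1g, Cnp, Ugt8a, Csf1r, Kcnc1, Tspan18, Rorb, Ntng1, Synpr, Ifit3, Idi1, Dhcr7, Ndufv1, Rplp0, Col3a1, Grn, Man2b1, Npas2, Drd1, Htr4, Kdm5c and Ddx3x. With the mean of all probe sets of a gene, Gjc3 (adjusted p = 0.241, in a range from 0.000618) did not pass, nor did Adk, which also failed with x_at and s_at probe sets left out (adjusted p = 0.709, in a range from 0.00161).

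The KA arrays at 8 h also stood apart in sex-linked genes, which moved with the lists called at this time. Xist, the noncoding RNA of X inactivation, lay between 7.39 and 8.71 (log2) on the 3 KA arrays and between 4.19 and 4.67 on the 9 other arrays. It was at least 11.4-fold higher (log2 change as fitted 3.53 ± 0.23, adjusted p = 5.85e-08), with 2 of the 3 control arrays at 8 h above background. The Y-linked Eif2s3y lay between 5.57 and 6.83 on the KA arrays and between 7.46 and 8.09 elsewhere. Kdm5d, also on the Y chromosome, lay between 5.07 and 6.10 against 6.43 to 6.95. Of 4 measured sex-linked genes, 1 rose and 2 fell [1 and 3]. The labels give no sex. With the genes of the X and Y chromosomes left out, a choice made after seeing the data, 2345 genes changed at 8 h. That count keeps any gene on another chromosome that differs between the sexes. The pattern covers the whole KA group at 8 h. A difference in sex, if present, therefore cannot be told apart from KA at 8 h, nor in the difference between the times.

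**Figure D1:**
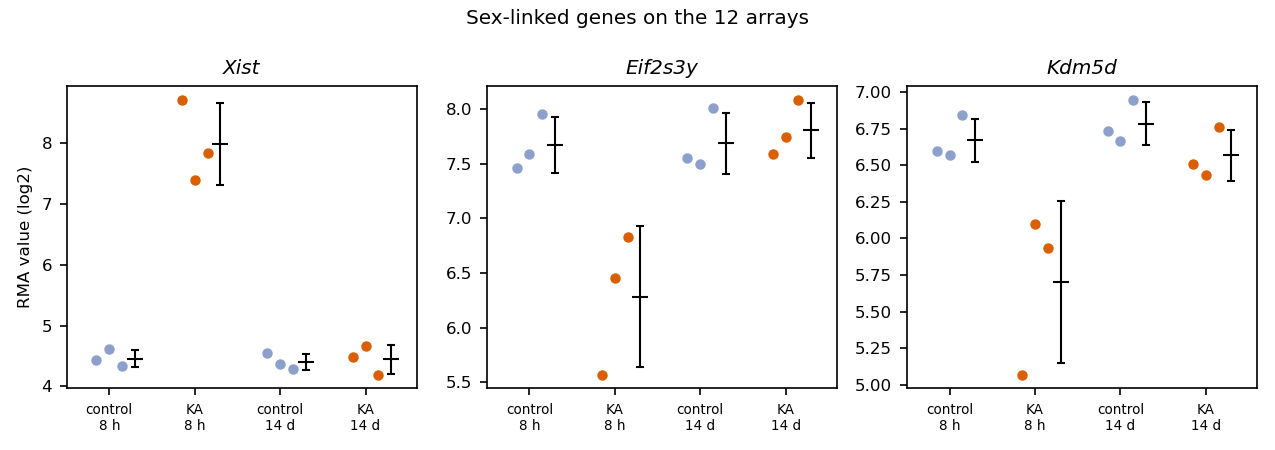
Log2 RMA values of Xist, Eif2s3y and Kdm5d on each of the 12 arrays, by group on the horizontal axis, with points for arrays and a bar for the mean and SD of the group (n = 3). Xist lies at 7.39 or higher on the 3 KA arrays at 8 h and at 4.67 or lower on the 9 others.

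The comparison at 14 d shows which transcripts differed at the later time, when spontaneous seizures are known to occur in models of this kind. The 6 largest fitted rises were those of glial, complement and neuronal genes. Cst7, an inhibitor of cysteine proteases, was at least 13.5-fold higher after KA (log2 change as fitted 4.06 ± 0.13, SE, n = 3 per group, adjusted p = 4.85e-11), with 0 of 3 control arrays above background, and Lyz2, lysozyme, was 8.75-fold higher. Serpina3n, a protease inhibitor of reactive astrocytes, was 5.30-fold higher and C4b, a complement component, 4.85-fold higher. Nptx2 was 5.00-fold higher (log2 change 2.32 ± 0.33, and 2.94 or 7.66-fold without KA 14 d replicate 2) and Penk, the precursor of enkephalins, 4.92-fold higher (log2 change 2.30 ± 0.23). The largest falls were smaller. Fibcd1, a marker of CA1 pyramidal cells, was 1.94-fold lower, Ankrd63 1.85-fold, Rskr at least 1.68-fold, Fxyd7 1.72-fold, Lrrtm1, a synaptic adhesion protein, 1.71-fold, and Pvalb, the calcium buffer of a class of interneurons, 1.64-fold lower (log2 change -0.71 ± 0.11).

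Of the genes tested, 354 changed at 14 d (2.56%), of which 275 rose and 79 fell. Falls at 14 d numbered 31 without control 14 d replicate 2, 32 without control 14 d replicate 3, 47 without KA 14 d replicate 1, 138 without KA 14 d replicate 3, 120 with median centring and 39 with only the 14 d groups in the fit. They numbered 839 with array weights (1260 rose), 169 with the replicate block (407 rose), 132 with all probe sets tested and 24 at an adjusted p under 0.01. By at least 2-fold, 49 genes rose and 0 fell, and 0 were at least 2-fold lower at an unadjusted limma p under 0.05. Of the changed genes, 353 showed no overlap between KA and control arrays, and 16.5% of all genes showed none, where chance gives 10%. Genes changed at 14 d numbered 196 without control 14 d replicate 2, 211 without control 14 d replicate 3 and 228 without KA 14 d replicate 1. With the third array of each group left out, they numbered 299 (219 rose and 80 fell).

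Activated microglia and phagocyte genes rose in 16 of 20 cases at 14 d [18 adjusted over the list alone], with a median log2 change of 0.96 (camera adjusted p = 4.79e-52). Cd68 was 3.86-fold higher and Ctsd, a lysosomal protease, 2.61-fold higher. Aif1, a microglial marker, was 1.80-fold higher (log2 change 0.85 ± 0.12, adjusted p = 0.000607). Homeostatic microglia genes rose in 7 of 10 cases [8], with a median of 0.72 (adjusted p = 2.60e-16). Fcrls was 2.84-fold, Olfml3 2.46-fold and Csf1r, the receptor that sustains microglia, 1.75-fold higher. Complement genes rose in 6 of 8 cases [7], with a median of 1.83 (adjusted p = 8.32e-23). The C1q subunit genes C1qa and C1qb were 4.72-fold and 3.68-fold higher. Reactive astrocyte genes rose in 10 of 19 cases [13], with a median of 0.49 (adjusted p = 9.22e-22), Vim, an intermediate filament gene, by 4.20-fold and Gfap by 3.36-fold (log2 change 1.75 ± 0.13). Extracellular matrix remodelling genes rose in 3 of 14 cases [5] (adjusted p = 9.61e-05), namely Col3a1 (2.50-fold), Col1a1 and Sparc. Of 14 purinergic and adenosine genes, P2ry6, a UDP receptor, rose 1.38-fold [5 rose adjusted over the list alone], and the list moved up (adjusted p = 1.29e-05). The calls of these 6 lists held with an estimated correlation, but with larger camera adjusted p-values. These were 0.000373 for activated and for homeostatic microglia genes, 0.00159 for complement and 0.000584 for reactive astrocyte genes. They were 0.0123 for extracellular matrix genes and 0.00765 for purinergic and adenosine genes.

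Of the calls lost with an estimated correlation at 14 d, 6 were upward. Interferon response genes rose in 5 of 11 cases [7], with a median of 0.79 (adjusted p = 5.59e-13, and adjusted p = 0.0822 with an estimated correlation). The major histocompatibility genes H2-D1 and H2-K1 were 2.90-fold and 2.75-fold higher, H2-D1 at 3 of the 4 probe sets past the filter with the same sign, and Ifi27l2a, Ifitm3 and Oasl2 rose too. Astrocyte markers rose in 5 of 13 cases [8] (adjusted p = 7.13e-11, and adjusted p = 0.0988 with an estimated correlation), with Aqp4, a water channel, 1.91-fold higher, and Aldh1l1, Atp1b2, S100b and Sox9. Cytokine and chemokine genes rose in 2 of 14 cases [3] (adjusted p = 2.12e-05, and adjusted p = 0.140 with an estimated correlation), namely Ccl6 (1.91-fold) and Ccl5, which lay above background on 1 of 3 KA and 0 of 3 control arrays, while Il1b differed by 0.31 ± 0.12 (log2, adjusted p = 0.241). Delayed activity-induced genes rose in 6 of 20 cases [9] (adjusted p = 1.39e-09, and adjusted p = 0.251 with an estimated correlation). KA 14 d replicate 2 lay below the 2 other KA arrays in Nptx2 (6.74 against 8.53 and 8.64, log2), Bdnf (6.49 against 7.27 and 7.76), Inhba (5.43 against 6.32 and 6.98) and Rgs2 (8.47 against 9.07 and 9.55), and without it the list had an adjusted p of 2.16e-20. Bdnf was 2.25-fold higher (log2 change 1.17 ± 0.21, adjusted p = 0.00612) and Rgs2, a regulator of G protein signalling, 2.07-fold. Inhba was 2.69-fold higher at the probe set used and changed by -0.50 (log2) at its other one. With the mean of both, it did not pass (adjusted p = 0.0955, in a range from 5.25e-07 to 0.0955 over the alternatives). Neuropeptide genes rose in 2 of 14 cases [4] (adjusted p = 0.00560, and adjusted p = 0.126 with an estimated correlation), namely Penk and Npy (2.52-fold, log2 change 1.33 ± 0.21), and did not pass as a list without control 14 d replicate 3 (adjusted p = 0.0535). KA 14 d replicate 2 was also the lowest KA array in Penk (8.26 against 9.22 and 9.53, log2) and Npy (9.59 against 10.82 and 10.57).

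The immediate early genes moved up as a list at 14 d (median 0.22, adjusted p = 0.000717, and adjusted p = 0.437 with an estimated correlation), though 0 of 20 passed singly in limma [3 rose adjusted over the list alone]. At an unadjusted p under 0.05, 7 were higher and 1 lower. Fos differed by 1.36 ± 0.50 (log2, adjusted p = 0.223) and Arc by 0.45 ± 0.24 (adjusted p = 0.471). The call of this list rested on KA 14 d replicate 3, without which it did not pass (adjusted p = 0.240). That array lay above the 2 other KA arrays in Fos (8.26 against 5.54 and 5.56, log2), Fosb (8.87 against 6.42 and 6.00), Arc (8.84 against 7.63 and 7.67) and Egr1 (10.04 against 8.93 and 8.82).

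Downward calls at 14 d numbered 7, all lost with an estimated correlation. Of 8 CA1 pyramidal markers, Fibcd1 fell [3 fell adjusted over the list alone], with a median of -0.30 (adjusted p = 0.00115, and adjusted p = 0.140 with an estimated correlation). Of 12 voltage-gated potassium and HCN channel genes, Kcnq3 (1.44-fold) and Kcnq5 (1.26-fold) fell [4], both subunits of the M-current channel (list adjusted p = 0.00752, adjusted p = 0.274 with an estimated correlation, and 0.0589 without KA 14 d replicate 2). Of 17 voltage-gated sodium and calcium channel genes, Scn2b fell 1.27-fold [4] (list adjusted p = 0.00200, and adjusted p = 0.315 with an estimated correlation). Of 17 synaptic vesicle genes, Syt1, the calcium sensor of release, fell 1.27-fold [1] (list adjusted p = 0.00216, adjusted p = 0.460 with an estimated correlation, and 0.107 without KA 14 d replicate 2). No single gene passed in the 3 other lists. These were the oligodendrocyte and myelin genes (adjusted p = 0.00428, and adjusted p = 0.315 with an estimated correlation), the choroid plexus markers (0.0316 and 0.621) and the mitochondrial respiratory chain genes (0.0408 and 0.658). At an unadjusted limma p under 0.05, their members that were lower numbered 4, 0 and 0 in that order. The oligodendrocyte list did not pass without control 14 d replicate 3 (adjusted p = 0.0546). The choroid plexus list did not pass without control 14 d replicate 1 (0.592) or KA 14 d replicates 2 (0.0785) and 3 (0.0980), nor the mitochondrial list without control 14 d replicates 1 (0.0632) and 3 (0.0829) or KA 14 d replicate 2 (0.971).

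Further lists at 14 d did not pass, of which 4 did so with 1 array left out (interneuron, endothelial and mural, cholesterol synthesis and CA3 pyramidal genes, with adjusted p from 0.000359 to 0.0335). Of 11 dentate granule cell markers, Pdzd2 (1.56-fold) and C1ql2 (1.39-fold) rose and Dsp fell [2 and 1]. Calb1 differed by -0.21 ± 0.10 (log2, adjusted p = 0.386). Pvalb fell among 15 interneuron markers [2 rose and 4 fell adjusted over the list alone], and Gad1 differed by -0.12 ± 0.11 (adjusted p = 0.759). Without KA 14 d replicate 2, it differed by 0.02. Cdkn1a, an inhibitor of the cell cycle, rose 2.11-fold among 16 heat shock and stress genes [2]. Zfp36l1 (1.47-fold) and Zfp36l2 rose among 22 genes of cytoplasmic polyadenylation and the poly(A) tail [2], and Cpeb4 differed by -0.24 ± 0.11 (log2, adjusted p = 0.351). Lamp5 fell among 8 cortex and amygdala markers [2], and Gusb rose among 10 reference genes [1]. No member of 20 glutamate receptor, 10 GABA-A receptor, 11 neurogenesis, 16 cell cycle or 11 cholesterol synthesis genes passed in limma, and at an unadjusted p under 0.05 the members of these lists numbered 2 higher and 4 lower, 1 and 1, 2 and 0, 0 and 1, and 2 and 0. Median and mean differed in sign for the poly(A) tail genes and the reference genes.

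Some of the smaller calls at 14 d ended when 1 of the 12 arrays was left out. The call of Scn2b was lost with 11 of them left out in turn (adjusted p up to 0.195, without control 14 d replicate 3), that of Lrrtm1 with 9 (up to 0.184, without the same array) and that of Kcnq5 with 7 (up to 0.150, without KA 14 d replicate 1). The call of P2ry6 was lost with 5 (up to 0.158, without control 14 d replicate 1), that of C1ql2 with 4 (up to 0.146, without KA 14 d replicate 1) and that of Syt1 with 4 (up to 0.0952, without control 14 d replicate 3). Zfp36l1 lost its call with 3 (up to 0.0875, without control 14 d replicate 1), Fxyd7 with 2 (up to 0.111, without control 14 d replicate 2) and Pdzd2 with 1 (0.0515, without KA 14 d replicate 1). Over all alternatives, the adjusted p of these 9 genes ranged from 3.37e-06 to 0.195. Of 23 further genes named, 12 lost their call without 1 array, with an adjusted p up to 0.172 (Sox9 without control 14 d replicate 1) in a range from 6.31e-06 over all alternatives. They were Col1a1, Sparc, Ifi27l2a, Oasl2, Aldh1l1, Atp1b2, S100b, Sox9, Ccl5, Dsp, Zfp36l2 and Dusp14. With only the 14 d groups in the fit, Scn2b, Lrrtm1, Kcnq5, P2ry6, Syt1 and Fxyd7 did not pass.

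**Figure D2:**
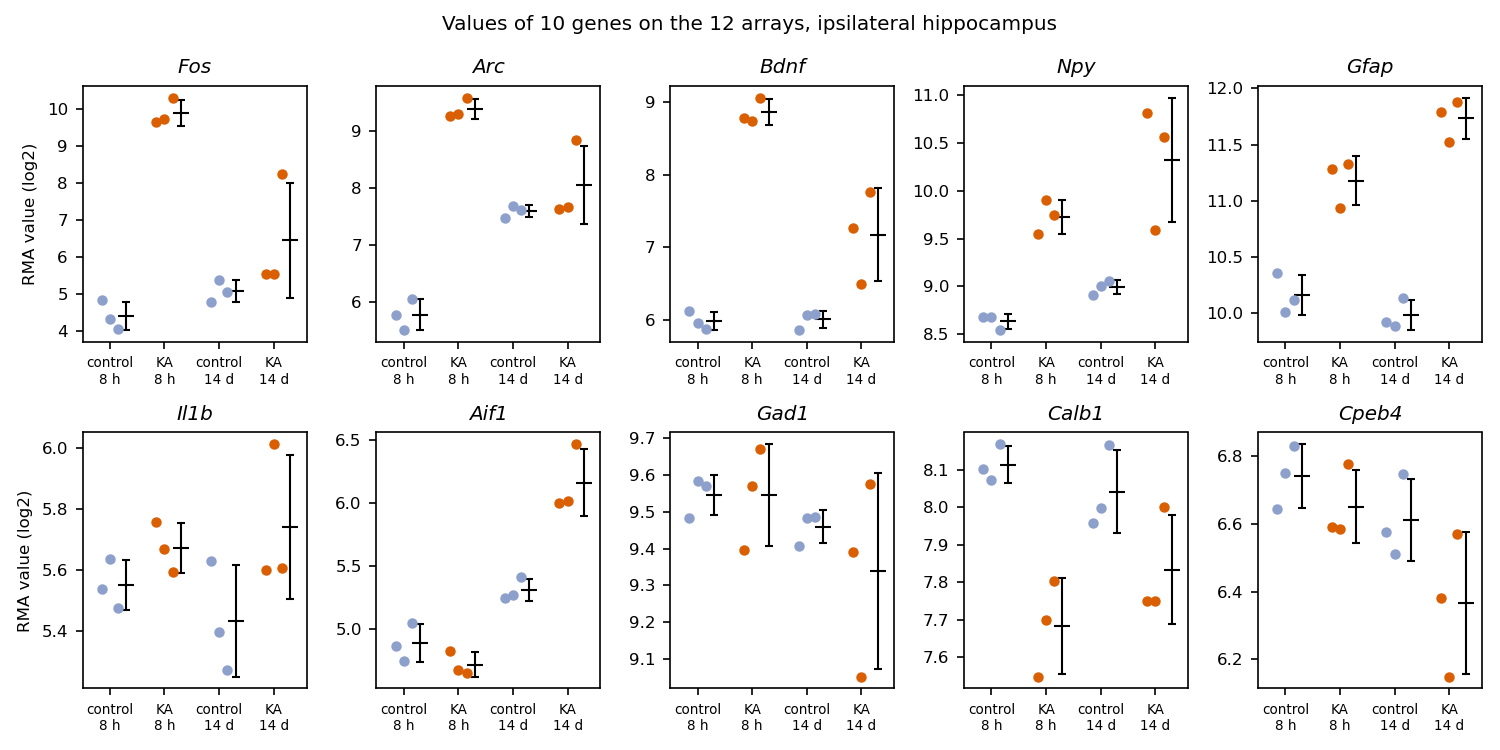
Log2 RMA values of 10 genes on each of the 12 arrays, by group on the horizontal axis, with a separate vertical scale for each gene, points for arrays and a bar for the mean and SD of the group (n = 3). Fos averages 9.91 in the KA group at 8 h against 4.42 in its controls, and Gfap is higher after KA at both times.

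**Figure D3:**
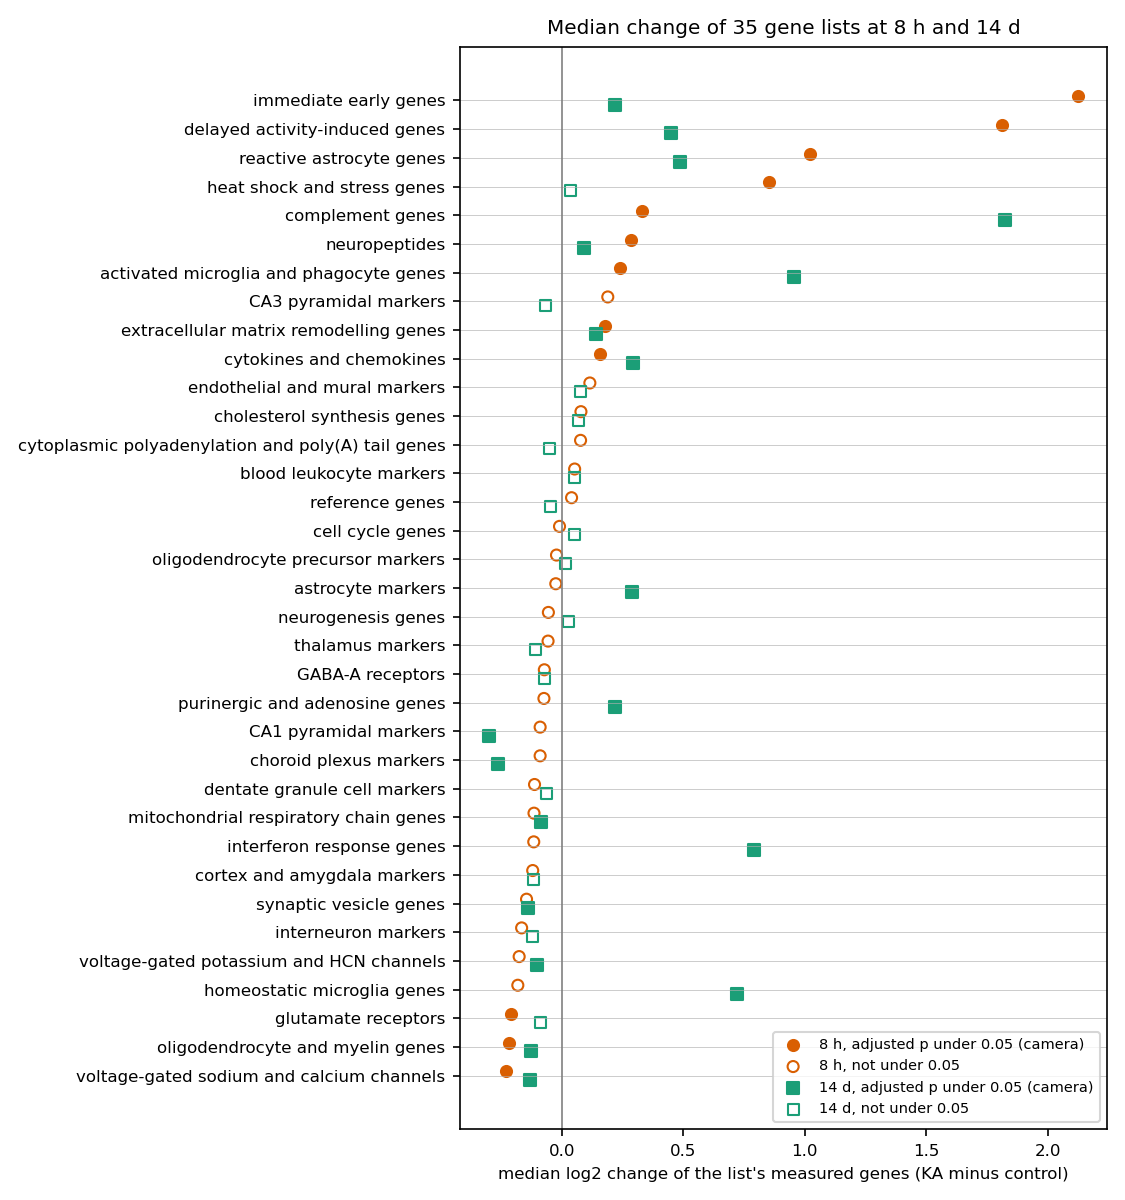
Median log2 change (KA minus control, horizontal axis) of the measured genes of 35 lists at 8 h (circles) and 14 d (squares), filled where the camera adjusted p was under 0.05 with the preset correlation. Immediate early genes lie at 2.12 at 8 h and 0.22 at 14 d, and complement genes at 0.33 and 1.83.

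The difference between the changes at 14 d and 8 h was tested as an interaction. A sign of RNA quality, the 3' minus 5' signal of Actb (log2), differed between the times, with means of -0.30 ± 0.015 (SD, n = 3) in the controls and -0.30 ± 0.042 in the KA group at 8 h, and -0.43 ± 0.021 and -0.47 ± 0.047 at 14 d. Activated and homeostatic microglia genes changed more upward at 14 d as lists, and immediate early and heat shock genes less. Relative to 8 h, the change at 14 d was higher by 3.83 ± 0.18 (log2, SE) for Cst7 (adjusted p = 1.93e-08), by 2.67 ± 0.28 for Lyz2 and by 2.02 ± 0.16 for C1qa. Cst7 lay above background on 0 of the 3 arrays of each 8 h group, so that its difference rests on the arrays at 14 d. For Trim30d, a member of the TRIM family, it was higher by 2.35 ± 0.52 (adjusted p = 0.0132, and 0.0904 with a trended and robust prior, the highest of a range from 0.000119 over the alternatives). The SD of Trim30d over the 8 h controls was 1.17, with control 8 h replicate 1 at 6.30 (log2) and the 2 others at 4.21 and 4.34, and without that array the difference was 1.67. The change was lower at 14 d for Hspa1b (-4.59 ± 0.28, adjusted p = 1.47e-07, above background on 1 of 3 arrays in each 14 d group), Fos (-4.13 ± 0.71) and Fosb (-3.62 ± 0.66, adjusted p = 0.00372, and 0.0533 with a trended and robust prior, the highest of a range from 1.38e-10). Without KA 14 d replicate 3, which stood above the other KA arrays at 14 d, the differences were -5.03 for Fos and -4.51 for Fosb. It was also lower for Xist (-3.48 ± 0.32 as fitted), whose high values lay on the KA arrays at 8 h and which was above background on 2 of 3 control and 0 of 3 KA arrays at 14 d. In all, 764 genes differed between the times, 340 with a higher and 424 with a lower change at 14 d. The split was 188 higher and 320 lower without control 14 d replicate 2, and it turned without KA 14 d replicate 2 (496 higher and 406 lower) and with array weights (1252 and 916). Genes whose change differs between 8 h and 14 d numbered 508 without control 14 d replicate 2, and 594 with the third array of each group left out.

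By list, the change at 14 d was the higher one for 14 of 20 activated microglia and phagocyte genes [15 adjusted over the list alone] (camera adjusted p = 4.00e-18), 8 of 10 homeostatic microglia genes [8] (adjusted p = 4.52e-12) and 2 of 14 purinergic and adenosine genes, P2ry12 and Adk [2] (adjusted p = 0.000208). It was the lower one for 15 of 20 immediate early genes [16] (adjusted p = 3.10e-22, and 2.49e-33 without KA 14 d replicate 3) and 10 of 16 heat shock and stress genes [10] (adjusted p = 4.54e-15). Among 19 reactive astrocyte genes, 7 were lower and 1, Gfap, higher [8 and 2] (adjusted p = 1.63e-05). These 6 calls held with an estimated correlation, but with larger camera adjusted p-values. These were 0.0101 for activated microglia and for heat shock genes, 0.00239 for homeostatic microglia and 0.0239 for purinergic genes. They were 0.0428 for immediate early and for reactive astrocyte genes. P2ry12 is a member of both the homeostatic microglia and the purinergic lists, and Hspb1 of both the reactive astrocyte and the heat shock lists. The delayed activity-induced genes were lower in 15 of 20 cases [19] (adjusted p = 1.19e-25, and adjusted p = 0.0501 with an estimated correlation). Complement genes were higher in 5 of 8 cases and lower for C5ar1 [5 and 1] (adjusted p = 5.75e-06, and adjusted p = 0.0607 with an estimated correlation). Interferon response genes were higher in 4 of 11 cases [8] (adjusted p = 3.15e-08, and adjusted p = 0.178 with an estimated correlation), namely H2-D1, H2-K1, Ifit3 and Oasl2. In the 8 h controls, replicate 1 lay above the 2 others in Ifit3 (8.57 against 7.29 and 7.14, log2) and Ifitm3 (8.78 against 7.72 and 7.68), and without it the list had an adjusted p of 5.48e-09. Astrocyte markers were higher in 3 of 13 cases and lower in 1 [7 and 1] (adjusted p = 1.63e-05, and adjusted p = 0.294 with an estimated correlation). Aqp4, Fgfr3 and Slc4a4 were higher and Sox9 lower. Of 14 neuropeptide genes, Crh, Nts and Sst were lower and Penk higher [3 and 1] (adjusted p = 0.0312, and adjusted p = 0.210 with an estimated correlation). The CA3 pyramidal markers Nectin3 and Tspan18 were lower [2] (list adjusted p = 0.0312, and adjusted p = 0.719 with an estimated correlation). The neuropeptide list did not pass without control 8 h replicate 3 (0.0707), control 14 d replicate 2 (0.0694), or KA 14 d replicates 2 (0.181) and 3 (0.0673). The CA3 list did not pass without KA 8 h replicate 3 (0.127), control 14 d replicate 3 (0.0843) or KA 14 d replicate 2 (0.226). With 1 array left out, 4 lists that had not passed did so (poly(A) tail, glutamate receptor, choroid plexus and dentate granule cell genes, with adjusted p from 0.000704 to 0.0473). Of 54 further genes named for this difference, 13 lost their call without 1 array, with an adjusted p up to 0.125 (Penk without KA 14 d replicate 1) in a range from 0.000114 to 0.205 over all alternatives. They were Gfap, Oasl2, Slc4a4, Sox9, Penk, Nectin3, Nptx2, Lrrtm1, Btg2, Adamts1, Zfp36l1, Fibcd1 and Eif2s3y. Adk, Htr1a, Cacna1d and Grik2 did not pass with the mean of all probe sets of a gene.

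The genes changed at the 2 times overlapped. Rises at both times were shared by 108 genes, where independent lists of 1097 and 275 genes would share 21.8, and falls by 53, where lists of 1323 and 79 would share 7.54. No gene rose at 8 h and fell at 14 d at the limma threshold, where 6.26 would be shared, and 42 genes moved so at an unadjusted p under 0.05 at both times. There were 11 genes that fell at 8 h and rose at 14 d, where 26.3 would be shared. They included the homeostatic microglia genes Csf1r, P2ry13, Selplg and Tmem119 and the lysosomal genes Grn and Man2b1, named after their values were seen. Across genes, which are not independent replicates, the log2 changes at the 2 times correlated at Pearson r = 0.373 and Spearman rho = 0.308. The count of genes changed in the same direction at both times, 161, was 92 without control 14 d replicate 2 and 100 without control 14 d replicate 3.

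**Figure D4:**
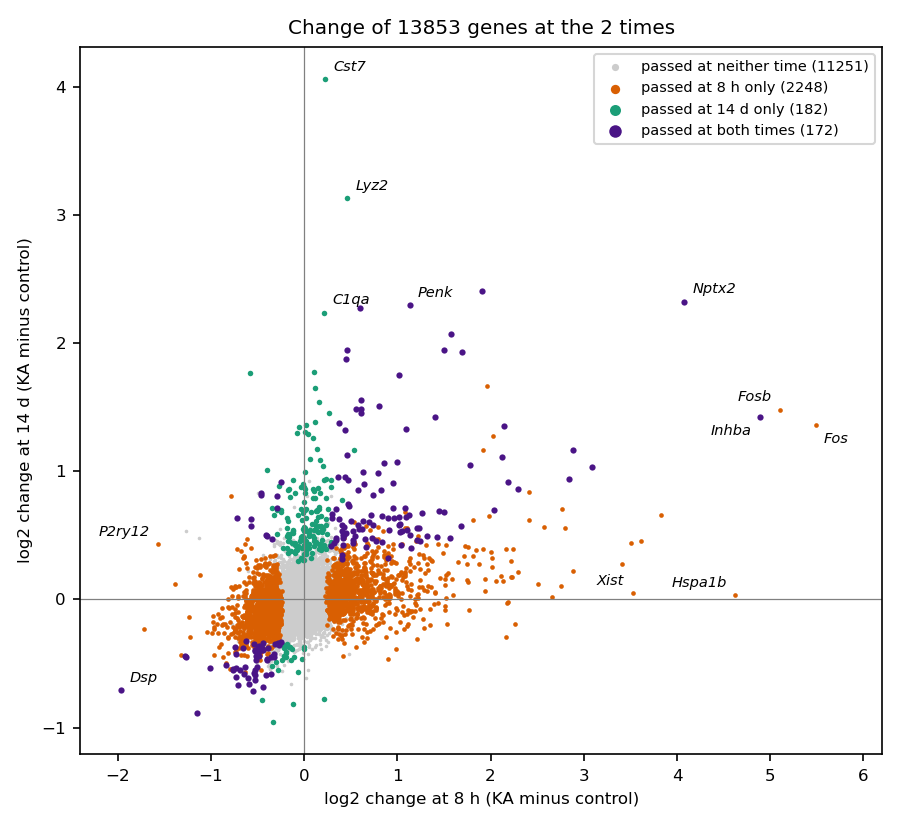
Log2 change (KA minus control) of each of 13853 genes at 8 h (horizontal axis) and 14 d (vertical axis), coloured by the times at which the gene passed an adjusted p under 0.05. In all, 172 genes passed at both times, 161 of them in the same direction.

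The control groups of the 2 times were compared as the background against which both KA groups were measured. The 3' minus 5' signal of Actb moved with this comparison, at -0.30 ± 0.015 (SD) in the 8 h controls and -0.43 ± 0.021 in the 14 d controls, while that of Gapdh was -0.12 ± 0.025 and -0.081 ± 0.048. Controls at 14 d had higher levels of the activity-regulated genes Arc and Egr1, a zinc finger transcription factor, by 3.54-fold (log2 difference 1.82 ± 0.24, SE, n = 3 per group, adjusted p = 0.000996) and 3.08-fold. Fabp7, a fatty acid binding protein of radial glia and astrocytes, was 2.22-fold higher and Serpinh1, a collagen chaperone, 2.09-fold higher at 14 d. Cdkn1a was 6.16-fold lower at 14 d (log2 difference -2.62 ± 0.14, adjusted p = 1.44e-07), Sgk1, a kinase induced by glucocorticoids, 2.97-fold lower, Smim3 2.72-fold and Sgk3 2.22-fold lower. In all, 249 genes differed, 155 higher and 94 lower at 14 d, and with cyclic loess the split of the genes that differ between the control groups was 188 higher and 185 lower. Without control 14 d replicate 3 it turned to 49 higher and 56 lower, and among genes that differed by at least 2-fold it was 4 higher and 5 lower. All 249 showed no overlap between the groups, against 25.1% of all genes, where chance gives 10%.

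Between the control groups, homeostatic microglia genes were higher at 14 d in 3 of 10 cases [5 adjusted over the list alone], namely Cx3cr1, Olfml3 and P2ry12 (camera adjusted p = 0.000266, and adjusted p = 0.0558 with an estimated correlation). The immediate early genes Arc, Egr1 and Nr4a2 were higher, 3 of 20 [5 higher and 1 lower] (adjusted p = 0.0193, and adjusted p = 0.944 with an estimated correlation). Of 13 oligodendrocyte and myelin genes, Ugt8a was higher [6] (list adjusted p = 0.0143, and adjusted p = 0.944 with an estimated correlation). Activated microglia and phagocyte genes moved up as a list with 0 of 20 past the limma threshold [3], and 6 were higher at an unadjusted p under 0.05 (list adjusted p = 0.0160, and adjusted p = 0.944 with an estimated correlation). Interferon response genes moved down with 0 of 11 past it [5], and 5 were lower at an unadjusted p under 0.05 (list adjusted p = 0.00913, and adjusted p = 0.944 with an estimated correlation). That call rested on control 8 h replicate 1, which lay above the 2 others in Ifit3, Ifitm3 and Trim30d, and without which the list did not pass (adjusted p = 0.298). The immediate early and activated microglia lists did not pass without control 8 h replicate 3 (0.0917 and 0.0904), nor the myelin list without control 8 h replicate 2 (0.113) or control 14 d replicate 3 (0.0808). Dentate granule cell markers and delayed activity-induced genes passed only without 1 array (0.00852 without control 14 d replicate 3 and 0.0419 without KA 14 d replicate 2). Of the 6 further genes named here, Olfml3, P2ry12, Nr4a2 and Per2 lost their call without 1 array, with an adjusted p up to 0.171 in a range from 0.000103 to 0.254 over all alternatives. Genes that differ between the control groups depended in number on single arrays. They numbered 86, 127, 87, 92 and 105 without control 8 h replicates 1 and 2 and control 14 d replicates 1, 2 and 3 in that order, and 421 and 411 without KA 14 d replicates 2 and 3. With the third array of each group left out they numbered 230.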

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

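The tests of the sex-linked pattern were chosen after the result was seen, and the counts over other splits of the arrays were planned. The differences given here between the changes at 14 d and 8 h passed an adjusted p under 0.05 in limma, as log2 differences with the change at 8 h subtracted.

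Among genes whose change was higher at 14 d, the difference was 3.83 for Cst7, 2.67 for Lyz2, 2.02 for C1qa, 1.67 for C4b, 1.43 for C1qb, 1.27 for Ctsd and 1.02 for Aif1. It was 2.0 for P2ry12, 1.38 for Olfml3, 1.09 for Csf1r, 0.70 for Fcrls, 0.72 for Aqp4 and 0.73 for Gfap. It was 2.35 for Trim30d (1.67 without control 8 h replicate 1), 1.38 for H2-D1, 1.19 for H2-K1, 0.88 for Col3a1 and 1.17 for Penk. Dsp differed by 1.26, Sphk2 by 1.48, Htr1a by 0.89, Ccdc177 by 0.83, Cacna1d by 0.55 and Grik2 by 0.53. Such a difference also takes in any difference between the control groups. Dsp lay at 8.84 or higher (log2) in the 8 h controls and at 8.37 or lower in the 14 d controls. It lay at 7.25 or lower in the KA group at 8 h and at 7.02 to 7.75 at 14 d. The larger part of the difference of Dsp therefore lies in the controls.

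The change was lower at 14 d for Hspa1b (-4.59), Fos (-4.13, and -5.03 without KA 14 d replicate 3), Fosb (-3.62, and -4.51 without the same array), Inhba (-3.47), Atf3 (-3.17), Arc (-3.16), Gadd45g (-2.66) and Crh (-2.65). It was lower for Nr4a2 (-2.46), Pcsk1 (-2.20), Nts (-1.85), Hspb1 (-1.84), Nptx2 (-1.76, and -1.14 without KA 14 d replicate 2), Bdnf (-1.71), C5ar1 (-1.53), Osmr (-1.27) and Lif (-1.16). Smaller differences were those of Ccl3 (-1.04), Lrrtm1 (-0.98), Btg2 (-0.96), Atf4 (-0.94), Adamts1 (-0.82), Cd44 (-0.79), Kcna4 (-0.76), Rskr (-0.69), Sst (-0.67), Zfp36l1 (-0.67) and Fibcd1 (-0.62). Arc lay at 6.04 or lower (log2) in the 8 h controls and at 7.47 or higher in the 14 d controls. It lay at 9.26 or higher in the KA group at 8 h and at 7.63 to 8.84 at 14 d. The larger part of the difference of Arc therefore lies in the controls.

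Of these genes, Cst7, Crh, Lif, Hspa1b, Nts, Adamts1, Rskr, Trim30d, Atf3, Ccl3 and Fos lay at or below background on some arrays, so the size of their difference is uncertain.

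By list, the median difference was -1.97 for immediate early genes, -1.41 for delayed activity-induced genes, -0.74 for heat shock and stress genes, -0.40 for reactive astrocyte genes, -0.19 for CA3 pyramidal markers and -0.085 for neuropeptides. It was 1.00 for homeostatic microglia genes, 0.98 for complement genes, 0.85 for activated microglia and phagocyte genes, 0.76 for interferon response genes, 0.40 for astrocyte markers and 0.22 for purinergic and adenosine genes. Probe sets without a gene symbol, which no comparison used, also gave signals. Of 10398 past the filter, 1332 changed at 8 h and 124 at 14 d.

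Of 100 relabellings of the arrays within the 2 times (drawn from 200), 7, the real one included, gave as many genes as the 764 found, with a highest other count of 1727, so chance cannot be excluded by this count. All 7 keep the 8 h groups whole, as 11 of the 100 do, and therefore carry the change at 8 h, a structure of the samples. The highest count among the relabellings that part them was 54. For the changes at 8 h (2420 genes), at 14 d (354) and between the control groups (249), the 10 splits of 6 arrays are too few for a share under 0.05. In each case 1 split, the real one, gave as many genes, and the highest other count was 0.

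Xist differed by -3.48 and Eif2s3y by 1.51 between the changes at the 2 times, which rests on the KA arrays at 8 h, and Xist lay at or below background on some of the others. A swap of samples between the groups was checked by whether another array reached the lowest Xist value of the KA arrays at 8 h. The count, 0 of the 9 other arrays, restates the pattern, so it cannot decide on an exchange of single samples. An exchange of whole groups runs against Fos, which seizures induce and which lay at 9.65 to 10.32 (log2) on these arrays, at 4.07 to 5.39 in both control groups and at 5.54 to 8.26 in the KA group at 14 d. RNA of animals of both sexes in each KA 8 h sample stays open, since the finding that on 3 of 3 arrays Xist lay above and Eif2s3y and Kdm5d below all other arrays, with the Y-linked genes above the filter level, largely restates the pattern. Regulation of these genes by kainic acid in male tissue stays open as well, because no KA group at 8 h is of known sex and the median log2 change of X-linked genes that escape inactivation (0.263 at 8 h) allows either explanation.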

How the results depend on the processing

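Of these alternatives, leaving out X and Y chromosome genes and leaving out the third array of each group were chosen after the result was seen. With all probe sets tested and no collapse to genes, 4843 changed at 8 h, 551 at 14 d, 1478 differed between the changes and 445 between the controls, where more features were tested. With the replicate block within each time (paired), 576 genes changed at 14 d, 1178 differed between the changes and 269 changed alike at both times. For the controls, the block was instead the replicate number over all groups, which is not a pairing within a time, and 570 genes differed. Array weights gave 2099 at 14 d, 2168 for the difference and 1336 for the controls, and their estimation stopped before convergence. The weight of KA 14 d replicate 1 was 5.04, against 0.33 and 0.38 for replicates 2 and 3. The weighted KA mean at 14 d therefore rests mostly on 1 array. With only the groups of the comparison in the fit, 543 genes differed between the controls. The cause of the shifts with the block, the weights and the smaller fit was not tested. Requiring at least 2-fold left 203, 49, 179 and 9 genes (8 h, 14 d, difference, controls), and an adjusted p under 0.01 left 1352, 170, 346 and 64, since these thresholds are stricter. With an estimated correlation, camera called 6 lists at 8 h, 6 at 14 d and 6 for the difference, and fry called 12 at 14 d.

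Leaving out 1 array at a time gave 1659 to 2748 genes changed at 8 h, 196 to 457 at 14 d (lowest without control 14 d replicate 2), 508 to 902 for the difference (lowest without the same array), 86 to 421 for the controls (lowest without control 8 h replicate 1, highest without KA 14 d replicate 2), and 92 to 219 genes changed alike at both times. Called lists ranged from 11 to 14, 16 to 20 and 11 to 13. The log2 change of Gad1 at 8 h turned to 0.0020 with median centring and 0.057 with cyclic loess, and ranged from -0.063 to 0.074 without 1 array. At 14 d it ranged from -0.24 to 0.024, positive without KA 14 d replicate 2. None of these passed, and the cause was not tested. Of the genes named with values under the naming rule, 45 of 45 called at 8 h, 30 of 40 at 14 d, 6 of 8 for the difference and 8 of 8 between controls kept their call under every alternative that gave gene values. Of the further genes named, 48 of 76, 11 of 23, 37 of 54 and 2 of 6 did so in that order. Signal near the background limits dim genes, which the filter did not all leave out. On every array of both groups, 345 of 13853 genes lay at or below background at 8 h and 699 at 14 d, and 2 and 1 of these were called.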

Other observations

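The gene lists described here, and the tests of the control groups and of the third arrays, were chosen after the result was seen. Lysosome genes rose in 12 of 15 cases at 14 d, with a median log2 change of 0.69 (camera p = 3.20e-30, and p = 6.78e-05 with an estimated correlation). Laptm5 rose by 1.35, Ctss, a cysteine protease, by 1.29, Ctsh by 1.17 and Grn, progranulin, by 0.92. At 8 h, Grn and Man2b1 fell. The change was higher at 14 d for 9 of 15 (median difference 0.74, p = 7.29e-17, and p = 0.000582 with an estimated correlation).

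Feedback regulators of MAP kinase signalling rose in 10 of 14 cases at 8 h, with a median of 0.97 (p = 3.18e-13, and p = 0.00840 with an estimated correlation). Without the 3 members that the lists of activity-induced genes also hold, 7 of 11 rose, with a median of 0.68 (camera p of 2.38e-09, and 0.00778 with an estimated correlation). The phosphatase genes Dusp6 (2.23 as fitted, at least 4.59-fold, with 1 of 3 control arrays above background), Dusp1 (2.22) and Dusp4 (1.81), which are those 3 members, rose, as did Spry2 (1.73), Errfi1 (1.60) and Spry4 (1.29). At 14 d, 1 of 14 rose, Dusp14 (0.59). Clock and PAR bZIP genes moved both ways at 8 h, where 6 of 14 rose and 5 fell. As a list they had a camera p of 0.596. Dbp (-0.97), Hlf (-0.71), Nr1d2 (-0.68), Per3 (-0.62) and Tef (-0.45) fell, while Bhlhe41 (0.83), Per1 (0.72), Arntl (0.72), Cry2 (0.70), Bhlhe40 (0.41) and Npas2 (0.33) rose. Of 10 serotonin and dopamine receptor genes, Drd1 (0.40) and Htr4 (0.39) rose and Htr1a fell at 8 h.

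Glucocorticoid-induced genes were lower in the 14 d controls than in the 8 h controls for 10 of 16 (median -0.63, p = 9.10e-28, and p = 0.000164 with an estimated correlation). Without Cdkn1a, Sgk1 and Fkbp5, which led to the idea, the median of the other 13 was -0.57, with 12 lower and 7 past the threshold (p = 6.54e-19, and p = 8.12e-05 with an estimated correlation). That glucocorticoid-induced genes are higher as a set in the 8 h controls describes the pattern and does not explain it. Time of day of dissection stays open, since 1 of 14 clock and PAR bZIP genes passed (Per2, 0.54, adjusted p = 0.0478). That call was lost without 1 array. A difference between array batches of the 2 times cannot be told apart from time, since 0 batches given by labels or files hold both control groups. Time since the injection, 8 h or 14 d, also differs between the control groups by design and cannot be told apart from these.

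The third arrays of the 4 groups deviated together from their group means, with correlations of 0.401 to 0.526. Array background moved with this pattern, since the third array had the lowest mean of the GC-rich background probe sets in 4 of 4 groups. The third array also had the lowest 3' minus 5' signal of Gapdh (log2) in each group. It was -0.147 and -0.132 in the control and KA groups at 8 h and -0.135 and -0.170 at 14 d. That of Actb was not lowest on the third array of any group. The 75th percentile of the values was highest on the third array of each group. Whether any of these measures accounts for the pattern or is part of the same deviation was not tested. A shared day or litter of the animals stays open, since 0 labels give a day or litter. Of the X-linked genes that escape inactivation, 2 of 4 rose at 8 h, Kdm5c (0.49) and Ddx3x (0.24), with a median of 0.263 over the list.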
